A study of Mus musculus with 6 samples.

How the data were processed

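Total RNA from 3 clones of AtT-20 cells with doxycycline-inducible rat PAM-1 was measured on Illumina MouseWG-6 v2.0 bead arrays after labelling with biotin, per the labels' protocols. Each clone contributed 1 array from control medium and 1 from doxycycline medium at 48 h. Each group thus held 3 arrays, 1 per labelled clone. Within a labelled clone there was no repeat culture. The labels do not state whether clones 6_1 and 6_2 were derived separately or share an origin. The groups may therefore hold fewer than 3 independent lines. The treatment protocol gives 4 µg/ml of doxycycline and the sample descriptions 4 mg/ml, and the labels do not settle which is right.

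The deposited table of the whole series holds a scanner signal per probe and array as an intensity on a linear scale, not background-subtracted, and beside each a detection p-value, per the file headers. The detection columns share one name and were matched to arrays by their place beside the signal, which was checked by the order of p within each array. BeadStudio and GenomeStudio are named in the submitters' processing notes, with no version. The authors' processed intensity values were also deposited. They were on a linear scale with array medians of 134.1 to 134.2 and had the same rank order as the scanner signals of the same arrays (Spearman 1), so they were not centred per gene. How the authors normalised them is not given in the sources used here. The scanner signals had medians of 122.3 to 140.9 and maxima of 68097 to 71549. No slide or scan information was used here, and 0 columns belonged to other series.

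Scanner signals were normalised with limma 3.58.1 in R 4.3.3. The neqc method estimated the background from the detection p-values, applied normexp with an offset of 16, quantile-normalised the arrays and took log2. A probe was kept when its detection p was under 0.01 on at least 3 of the 6 arrays, whichever group they were in, which left 16902 of 45281 probes. Log2 values below are of these normalised intensities. The neqc offset shrinks differences of dim probes, so folds near background are understated. Where a probe was not well above background (detection p of 0.01 or more) on every array of one group, only a bound is given as at least N-fold: the mean of the bright group against, per array of the dim group, the higher of the lowest normalised value among probes above background and the probe's own.

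Gene symbols came from the platform annotation, in which 34885 probes had 1 symbol, 18 several and 10378 none. Of the kept probes 14549 had 1 symbol, 5 several and 2348 none, and they stood for 9196 genes. Symbols were checked by Entrez number against the GRCm38.p6 reference annotation, which held 14535 of the kept probes, and 0 symbols changed. Every probe was tested. For gene-level tests the probe with the highest mean over the 6 arrays stood for its gene.

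The main comparison was fitted with lmFit and eBayes with clone as a block and medium as the effect, on 2 residual degrees of freedom plus 6.95 from the prior, two-sided, with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. Clone is a block because the labels state that each clone was kept in both media. As a check of the pairing, deviations from the group means correlated at 0.538 between the arrays of clone 14, -0.0211 for clone 6_1 and 0.139 for clone 6_2. The doxycycline arrays of clones 6_1 and 6_2 correlated more with the control array of the other one, at 0.229 and 0.426, so the values by themselves single out the pair of clone 14 only, and the pairing rests on the labels. The same fit gave the 3 differences between clones. Since a clone has 1 culture per medium, p-values between clones measure only the spread between these cultures. The similarity of the clones' responses was described by correlations across probes with no p.

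The comparisons, the test, the filter, 22 gene lists and the rule for naming genes were set before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 21 lists with enough measured members, of which 1 is not reported here. Counts of members are given adjusted over all probes and adjusted over the list alone. The naming rule took all Pam and Uhmk1 probes, the 12 largest rises and 12 largest falls among called probes with a symbol that moved the same way in every clone, 4 members of smallest p from each list that passed and from the granule cargo, copper and corticotrope identity lists, Pomc, Pcsk1, Cpe and Atp7a, and the 4 largest differences in each direction between clones. Genes named outside it were chosen after their values were seen, among them the members counted for lists that did not pass.

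A trend with gene span was examined with the span of each gene in GRCm38.p6, which was known for 99.9% of the measured genes. Span includes introns and is not transcript length. For each list 10000 random lists were drawn, each member replaced by one of the 100 genes nearest in span and mean level, and the list's median was placed among theirs. Families of genes sharing a symbol stem were examined only after the results were seen.

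The fits were tested on simulated arrays over 16902 probes, with the mean of each probe in each clone from the real arrays and variances drawn from the fitted prior. For doxycycline against control, 44 of 100 probes changed by 1 on the log2 scale and 100 of 100 changed by 2 were recovered, 5 of 149 calls were unchanged probes, and 0 calls were made with no change. For clone 14 against clone 6_1, simulated with the mean over the clones in place of each clone's own, the recovered numbers were 20 of 100 and 98 of 100. Of the simulated lists, over 9196 genes, 2 of 2 shifted lists and 0 of 19 unshifted lists were called. Noise was drawn independently for each probe and array. The simulated arrays thus lacked the correlation between genes and the array-wide trends of the real ones, and their error rates need not hold for the real arrays.

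Alternatives were no clone block, no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, no filter, a detection p of 0.05 on 3 arrays, 0.01 on all 6 arrays, eBayes with trend and robust settings, an unmoderated paired statistic, leaving out each clone in turn, an estimated correlation, the mean over a gene's probes and, added after seeing the data, removal of the gene span trend per array by lowess.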

Results

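Gene expression was measured in AtT-20 cells, a mouse pituitary tumour line of corticotropes that store peptides made from the Pomc precursor in secretory granules. The cells carried rat PAM-1 under a doxycycline-inducible promoter. PAM is peptidylglycine alpha-amidating monooxygenase, a copper-dependent enzyme of the granule membrane, and Uhmk1 is the protein kinase that the study's title pairs with it as a route from the granule to the nucleus. The clones, named 14, 6_1 and 6_2, were each kept for 48 h in control medium and in doxycycline medium, which gave 3 control arrays and 3 doxycycline arrays with 1 array per clone and medium. The labels give the doxycycline concentration as 4 µg/ml in one place and 4 mg/ml in another. Whether clones 6_1 and 6_2 have separate origins is not stated in the labels, so the 3 arrays per medium may stand for fewer independent lines. No doxycycline-treated cells without the transgene were analysed here. Effects of the drug and of induced PAM-1 therefore cannot be told apart in any comparison of the media.

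Of 45281 probes, 16196 to 17149 per array gave a signal above background at a detection p under 0.01, which is 35.8% to 37.9%, and 16902 probes that did so on at least 3 arrays were tested. Every doxycycline array had fewer such probes than the control array of its clone, 16464 against 17147 in clone 14, 16196 against 16851 in clone 6_1 and 16217 against 17149 in clone 6_2. Correlations between the normalised arrays ran from 0.940 to 0.989 across probes. The control array of clone 6_1 stood apart: it lay at 56.5 on the first principal component, which held 56.2% of the variance, against 18.7 and -11.2 for the other control arrays and -33.7, -21.8 and -8.51 for the doxycycline arrays of clones 14, 6_1 and 6_2. The number of arrays limits the precision of every value that follows.

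The mouse Pam gene was measured first. Its detected probe (ILMN_2626294) read 8.33 ± 0.14 on the log2 scale in control medium and 8.68 ± 0.17 with doxycycline (mean ± SD, n = 3 arrays each), a difference of 0.35 (SE 0.18) that did not pass the test (limma, adjusted p = 0.285). The difference was 0.18 in clone 14, 0.17 in clone 6_1 and 0.69 in clone 6_2. A further Pam probe (ILMN_1236965) was above background on 0 of 6 arrays. Where these mouse probes lie relative to the rat sequence is not given in the sources used here, so neither probe checks the induction of the transgene. Uhmk1 read 0.32 (SE 0.17) and 0.31 (SE 0.17) lower with doxycycline on its 2 tested probes, and neither passed (limma, adjusted p = 0.296 and 0.294). Both tested Uhmk1 probes lay near background, at 6.22 and 6.36 in control medium and 5.89 and 6.05 with doxycycline. The lowest values above background were 5.97 to 6.22 per array. Each of these probes was above background on 4 of the 6 arrays, so their differences carry little. The 2 other Uhmk1 probes were above background on 0 and 1 of the 6 arrays.

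The comparison of doxycycline with control medium asked which transcripts moved after 48 h in the medium meant to induce PAM-1. Slpi, which encodes the secreted leukocyte protease inhibitor, rose by 3.24 on the log2 scale (SE 0.27), or 9.47-fold, from 9.37 ± 1.11 to 12.62 ± 0.33 (mean ± SD, n = 3 arrays each; limma, adjusted p = 0.00448). It was higher in each clone, by 2.35 in clone 14, 3.84 in clone 6_1 and 3.53 in clone 6_2. Aqp1, the water channel aquaporin 1, rose on all 3 of its probes, by 1.72 (SE 0.19), 1.65 (SE 0.18) and 1.53 (SE 0.16), with adjusted p between 0.0136 and 0.0138. The aldehyde oxidase gene Aox3 fell from 7.99 ± 0.58 to a level not well above background on any doxycycline array, and was at least 3.47-fold lower (adjusted p = 0.00822).

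In total 32 probes rose and 21 fell, and all 53 moved the same way in the 3 clones. This follows largely from the call, since the test sets the mean change against the spread of the clones' changes. The rising probes stood for 22 named genes and the falling probes for 15, while 11 of the 53 had no gene symbol. The smallest change that passed was 1.05 on the log2 scale, or 2.07-fold, and 3761 probes had an unadjusted p under 0.05.

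The risen genes had varied functions. Wfdc1, which shares the whey acidic protein domain with Slpi, rose by 2.06 (SE 0.24). Krt73, a type II keratin, rose by 1.98 (SE 0.17) and 1.76 (SE 0.19) on its 2 probes, and Dmkn, which encodes the secreted protein dermokine, rose by 1.59 (SE 0.18), with its other probe also called. Ly6g6c, a membrane-anchored protein of the Ly6 family, was not well above background on any control array and was at least 2.36-fold higher with doxycycline (adjusted p = 0.0183). The histone variant genes H2al1e and H2al1m belong to a family of near-identical copies on the X chromosome, so their probes are uncertain as to the copy. H2al1e was at least 2.78-fold higher and H2al1m at least 1.56-fold higher, on probes not well above background on any control array (limma, adjusted p = 0.0136 and 0.0162). Rfx2, a transcription factor of ciliary genes, rose by 1.43 (SE 0.17) and the kinase gene Trp53rkb by 1.41 (SE 0.21), each on 1 of 2 tested probes. The remaining named rises were 2010204K13Rik at 1.46 (SE 0.19) and the long noncoding gene Rab26os at 1.44 (SE 0.20).

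The fallen genes included enzymes, channels and surface proteins. Krt23, a type I keratin, fell by 1.51 (SE 0.19, adjusted p = 0.0223), opposite to Krt73. Kcnc1, a voltage-gated potassium channel gene, fell by 1.46 (SE 0.22), and Lrrc17 by 1.44 (SE 0.23), close to the threshold at adjusted p = 0.0492. Tmprss2, a transmembrane serine protease, fell by 1.40 (SE 0.18) and the interleukin receptor subunit Il20ra by 1.33 (SE 0.19) on 1 of 2 tested probes. Plscr4, a phospholipid scramblase, fell by 1.28 (SE 0.17). Tox3, a nuclear protein of the HMG-box family, fell by 1.26 (SE 0.18) and was above background on 1 of the 3 doxycycline arrays. Rpe, an enzyme of the pentose phosphate pathway, fell by 1.20 (SE 0.17), as did St8sia4, a sialyltransferase that makes polysialic acid, by 1.20 (SE 0.18) on 1 of 2 tested probes. Stk39, a kinase that acts on ion cotransporters, fell by 1.18 (SE 0.17). Speer2 was not well above background on any doxycycline array and was at least 1.45-fold lower (adjusted p = 0.0260).

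**Figure D1:**
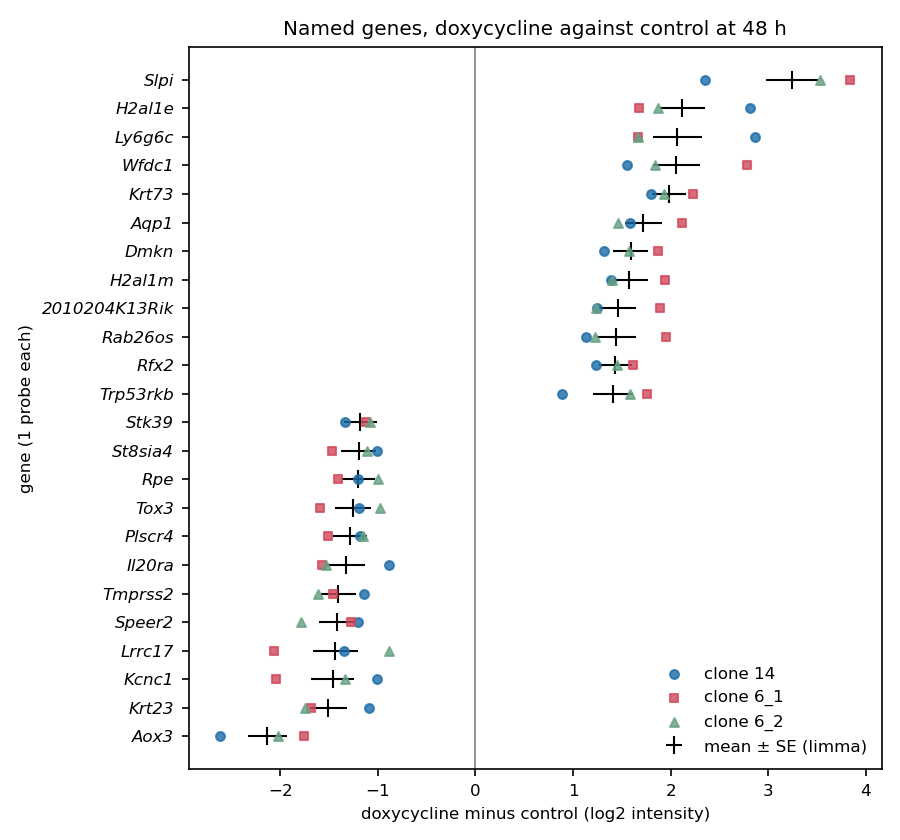
Difference between doxycycline and control medium on the log2 intensity scale (horizontal axis) for the 24 genes named by rule (vertical axis, 1 probe each), with coloured points for the 3 clones and a black tick and bar for the mean with the SE from limma. Means run from -1.51 for Krt23 to 3.24 for Slpi among genes above background in both media, and genes not well above background in one medium are drawn at their measured values.

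The calls rest on the moderated test and on the filter for dim probes: with no clone block 33 probes passed, all of them among the 53, with every probe on the array kept 1 passed, and with an unmoderated paired statistic 0 passed, with 1875 at an unadjusted p under 0.05. Without clone 14, 6_1 or 6_2 the count was 717, 78 or 400, and in the first and last of these fits limma's prior degrees of freedom were infinite, against 6.95 with all clones, so that every probe was given one common variance.

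Gene lists fixed before the data were examined were tested next, to ask which cell functions moved as groups. A gene's value in the lists is that of its brightest probe, also where it had others, as Mtf1, Kdm3a and Car9 with 3 tested probes each. Of 21 lists tested, 4 rose and 2 fell by limma's camera test with a preset correlation of 0.01 between genes, and 0 passed with an estimated correlation or by fry. The estimated correlation was -0.00099 for granule exocytosis and -0.0077 for mitochondrial chaperones, under the preset. Their unadjusted camera p still rose, from 0.00664 to 0.0942 and from 0.00446 to 0.0846. In that setting camera uses the 2 residual degrees of freedom, so for these lists the lost call does not come from correlation between genes. The largest shift was in the nuclear genes for oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria. Of its 60 measured genes 58 were higher with doxycycline and 52 were higher in all 3 clones, with a median change of 0.53 (adjusted p = 1.84e-15). Adjusted over the list alone 31 genes rose and 0 fell, whereas 0 passed over all probes. The estimated correlation between these genes was 0.637, and the list then had an adjusted p = 0.889 with an estimated correlation.

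Examples from this list were the ATP synthase subunit Atp5k at 1.38 (SE 0.23), above background on 1 of 3 control arrays, and the complex I subunits Ndufb7 at 1.00 (SE 0.19), Ndufa3 at 0.89 (SE 0.18) and Ndufa5 at 0.82 (SE 0.19), each with an adjusted p over all probes of 0.0547 to 0.0955. The median change of the list was 0.26 in clone 14, 0.87 in clone 6_1 and 0.36 in clone 6_2. Its median deviation from the mean of all arrays was -0.53 on the control array of clone 6_1, -0.27 on that of clone 6_2 and 0.08 on that of clone 14, and 0.31, 0.30 and 0.10 on the doxycycline arrays of clones 14, 6_1 and 6_2, which also had the fewer probes above background.

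The list of mitochondrial chaperones, proteases and translation rose too, with 23 of 29 genes higher and a median change of 0.23 (camera, adjusted p = 0.0234; adjusted p = 0.660 with an estimated correlation). Without clone 6_1 its median was 0.13 (adjusted p = 0.0266), and with the gene length trend removed 0.09. Adjusted over the list alone 0 of its genes passed, and the lowest p belonged to the mitochondrial ribosomal protein genes Mrps16 at 0.79 (SE 0.18), Mrpl11 at 0.70 (SE 0.21), Mrps12 at 0.66 (SE 0.20) and Mrpl12 at 0.73 (SE 0.22). In clones 14, 6_1 and 6_2 Mrpl11 changed by 0.39, 1.24 and 0.47 and Mrpl12 by 0.52, 1.36 and 0.30. Mrps16 changed by 0.51, 1.08 and 0.77 and Mrps12 by 0.23, 1.07 and 0.67. Interferon and antigen presentation genes rose with 14 of 16 higher and a median change of 0.35 (adjusted p = 0.000474; adjusted p = 0.660 with an estimated correlation). The 4 members that rose when adjusted over the list alone serve the loading of class I molecules: the immunoproteasome subunits Psmb10 at 1.36 (SE 0.23) and Psmb8 at 0.99 (SE 0.19), beta-2 microglobulin B2m at 1.10 (SE 0.25) and the peptide transporter Tap2 at 0.72 (SE 0.19). None of the 16 passed over all probes, and the interferon pathway factors Irf9 and Stat2 read -0.24 (SE 0.17) and -0.11 (SE 0.16).

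Copper handling and metallothionein genes, of interest because PAM needs copper, were higher in 13 of 15 cases with a median change of 0.36 (adjusted p = 0.00930; adjusted p = 0.889 with an estimated correlation). Adjusted over the list alone 4 rose: the copper chaperone Atox1 at 0.96 (SE 0.17), the metallothioneins Mt3 at 1.19 (SE 0.34) and Mt2 at 0.77 (SE 0.22), and their metal-responsive regulator Mtf1 at 0.81 (SE 0.25). Over all probes 0 passed. The copper pump Atp7a read -0.50 (SE 0.21, adjusted p = 0.206), with -0.22, -1.02 and -0.24 in clones 14, 6_1 and 6_2. Without clone 6_1 the median change of this list was 0.12 and the list no longer passed (adjusted p = 0.0739). The changes in clones 14, 6_1 and 6_2 were 0.20, 2.37 and 0.99 for Mt3, 0.33, 1.40 and 0.59 for Mt2 and 0.37, 1.61 and 0.44 for Mtf1, and without clone 6_1 their means were 0.59, 0.46 and 0.41.

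Granule exocytosis and docking genes fell, with 18 of 25 lower and a median change of -0.19 (adjusted p = 0.0279; adjusted p = 0.660 with an estimated correlation). Adjusted over the list alone 5 fell, among them the granule docking gene Sytl4 at -0.71 (SE 0.19), the active zone gene Rims2 at -0.61 (SE 0.18) and the calcium sensor Syt1 at -0.65 (SE 0.19), and over all probes 0 passed. Syt1 had 3 tested probes, and its value is that of the brightest. Unc13a, a priming factor, was another of the 5 and was above background on 3 of 3 control arrays and 0 of 3 doxycycline arrays. Glycolysis and hypoxia genes fell with 21 of 29 lower and a median change of -0.12 (adjusted p = 0.0481; adjusted p = 0.889 with an estimated correlation), led by the kinase Pdk1 at -0.67 (SE 0.17), the histone demethylase Kdm3a at -0.65 (SE 0.17) and the mitophagy receptor Bnip3l at -0.59 (SE 0.20), while the carbonic anhydrase Car9 read 0.49 (SE 0.18). In this list 0 genes passed when adjusted over the list alone or over all probes. Leaving out clone 6_2, which also leaves fewer arrays, ended the call of the exocytosis, glycolysis and mitochondrial chaperone lists (adjusted p = 0.101, 0.317 and 0.0521) at medians of -0.17, -0.10 and 0.30. Leaving out clone 6_1 ended that of glycolysis (adjusted p = 0.128) at a larger median, -0.18. The falls of 2 lists also hung on scaling and filter: glycolysis did not pass with median scaling (median -0.01, adjusted p = 0.702), cyclic loess (0.113), a detection p of 0.05 (0.0505) or the mean over probes (0.109), and exocytosis did not pass with no filter (median -0.01, adjusted p = 0.393) or a detection p of 0.05 (median -0.07, adjusted p = 0.165). Exocytosis passed with the mean over a gene's probes (camera, adjusted p = 0.0420) but at a median of -0.04. With median scaling it passed (camera, adjusted p = 0.0227) at a median of -0.10.

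Granule cargo and corticotrope identity lists did not pass. The cargo list had 8 of 16 genes higher, with a median change of 0.00 and an adjusted p = 0.799. Its medians in clones 14, 6_1 and 6_2 were -0.13, 0.07 and -0.21. Without clone 6_1 its median was -0.20, at percentile 0.76 of lists matched on gene span and level, against 45.4 with all clones. The list passed camera in no setting. Its processing enzyme Cpe read -0.51 (SE 0.18), Pcsk1 -0.27 (SE 0.27), Pcsk6 -0.51 (SE 0.20), the granin Scg3 -0.38 (SE 0.17) and Vgf 0.88 (SE 0.26), with adjusted p from 0.124 to 0.572. In clones 14, 6_1 and 6_2 Vgf changed by 0.67, 1.71 and 0.26, and Pcsk1 by 0.02, -1.16 and 0.34. Pcsk1 lay near background, at 6.46 in control medium and 6.19 with doxycycline, and was above background on 2 of 3 doxycycline arrays. Pomc read 0.08 (SE 0.16, adjusted p = 0.796) on a probe whose scanner signals of 58644 to 68204 lay close to the array maxima of 68097 to 71549, so its difference carries little, and its sign turned with cyclic loess, with the authors' values and with the gene length trend removed. The other Pomc probe read -0.17 (SE 0.20, adjusted p = 0.629). In the identity list (16 genes, adjusted p = 0.735) the corticotropin-releasing hormone receptor Crhr1 read 0.65 (SE 0.17), Neurod4 -0.72 (SE 0.21), Hdac2 -0.52 (SE 0.17) and Sstr5 0.46 (SE 0.18), none of which passed over all probes or when adjusted over the list alone.

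The other lists that were tested did not pass either. Adjusted p was 0.994 for PAM and Uhmk1 partners (11 genes), 0.799 for V-ATPase subunits (16), 0.843 for lysosome (23), 0.799 for endosome sorting (42), 0.843 for ER chaperones (27), 0.654 for ATF4 targets (36), 0.393 for cholesterol synthesis (18), 0.843 for cell cycle (39), 0.843 for immediate early genes (20), 0.840 for NRF2 targets (22) and 0.735 for channels, aquaporins and protease inhibitors (18). The last of these holds Slpi and Aqp1, its 2 genes that rose over all probes, and 4 that rose when adjusted over the list alone. Fkbp11 and Sec61b of the ER list rose when adjusted over the list alone, by 1.04 (SE 0.26) and 0.76 (SE 0.19), as did Ier3 by 1.05 (SE 0.20) and Osgin1 by 0.65 (SE 0.18), while Fos fell by 1.31 (SE 0.22), Cat by 0.83 (SE 0.18) and Slc7a11 by 0.68 (SE 0.17). In every remaining list of this group 0 members passed on either adjustment. Median, mean and camera direction differed in sign for the cargo, PAM partner, lysosome, ER chaperone, immediate early and channel lists. Markers of other cells were nearly absent: of the other pituitary lineages 3 of 20 genes were measured, Sox2, Sox9 and Gata2 (adjusted p = 0.945), and of 22 fibroblast, endothelial and immune markers only Kdr, at 0.19 (SE 0.18), too few for a list test.

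**Figure D2:**
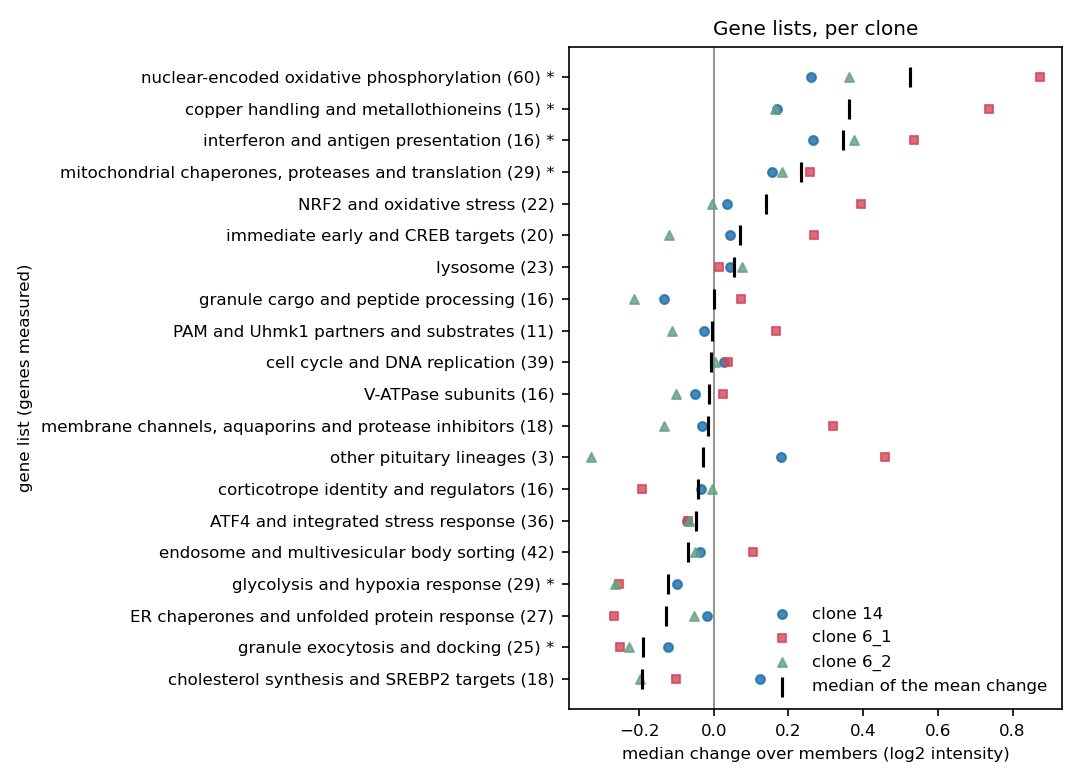
Median change with doxycycline over the measured members of each list (horizontal axis, log2 intensity), with the lists on the vertical axis and the number of measured genes in brackets, coloured points for the clones, black ticks for the median of the mean change and an asterisk for an adjusted p under 0.05 by camera. Oxidative phosphorylation has the highest median of the mean change, 0.53, and lies at 0.26, 0.87 and 0.36 in clones 14, 6_1 and 6_2.

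The change with doxycycline ran with gene span across genes. The Spearman correlation between change and span was -0.44 for the mean and -0.24, -0.46 and -0.29 in clones 14, 6_1 and 6_2, over 9183 genes, which are not independent replicates. Among the 919 genes with the shortest spans the median change was 0.31, and among the 919 with the longest -0.21. Among single arrays, the deviation from the mean of all arrays had a Spearman correlation with span of 0.46 on the control array of clone 6_1, 0.22 and -0.10 on the control arrays of clones 6_2 and 14, and between -0.34 and -0.23 on the doxycycline arrays. With this trend removed, a setting chosen after seeing the data, 3 lists passed: oxidative phosphorylation at a median of 0.37 (adjusted p = 8.21e-11), interferon and antigen presentation at 0.27 (adjusted p = 0.00740) and glycolysis and hypoxia at -0.23 (adjusted p = 0.00740). Exocytosis, copper handling and mitochondrial chaperones did not (adjusted p = 0.166, 0.0709 and 0.166), at medians of -0.13, 0.31 and 0.09. Among random lists matched on gene span and level, oxidative phosphorylation lay at percentile 100, copper handling at 99.4, and interferon at 99, above the central 95%, while mitochondrial chaperones at 95.8, exocytosis at 8.12 and glycolysis at 7.03 lay inside it. Without clone 6_1 these 6 lay at 100, 79.4, 99.5, 91.9, 4.71 and 0.27. ER chaperones at 0.31 and cholesterol synthesis at 0.2, which did not pass by camera, lay under their matched range with all clones and at 5.81 and 21.8 without clone 6_1.

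**Figure D3:**
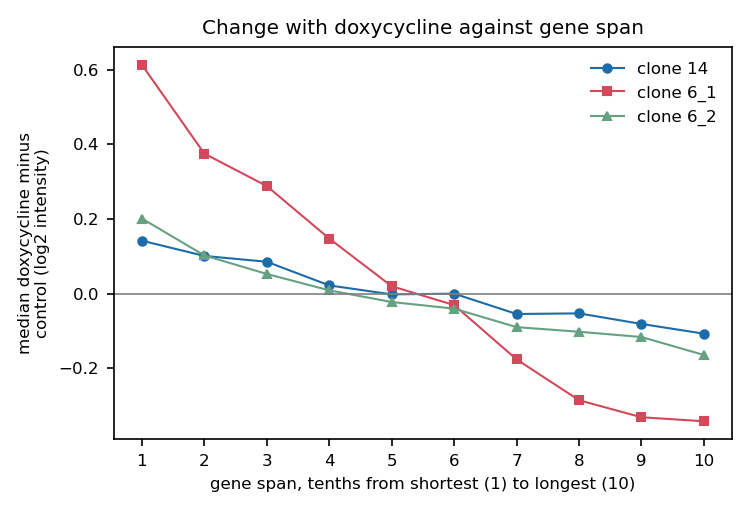
Median change with doxycycline (vertical axis, log2 intensity) in 10 groups of genes ordered by the span of the gene in the reference annotation (horizontal axis), with 1 line per clone. The medians fall from 0.14, 0.61 and 0.20 in the shortest group to -0.11, -0.34 and -0.16 in the longest for clones 14, 6_1 and 6_2.

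The clones were compared with each other to see how far apart the replicate lines lay with the medium held in the model. Clone 14 differed most, and its lowest gene against both others was Egr1, an immediate early transcription factor, at -3.97 (SE 0.30) against clone 6_1 and -3.91 (SE 0.30) against clone 6_2, or 15.6-fold and 15.1-fold (limma, adjusted p = 0.00157 and 0.00142, 2 arrays per clone). Egr1 read 7.68 and 7.47 in control and doxycycline medium in clone 14, 12.32 and 10.76 in clone 6_1, and 11.86 and 11.12 in clone 6_2. Fos, chosen after its values were seen, was lower in clone 14 by 2.12 against each of the others (SE 0.27). The DNA sensor gene Cgas was lower by 2.97 and 3.30 (SE 0.24), and the protocadherin Pcdh9 by 2.56 and 2.30 (SE 0.26). The channel gene Panx1 was not well above background in clone 14 and at least 3.96-fold and 4.02-fold lower there, and the antiviral factor Shfl at least 3.87-fold and 4.17-fold lower, against clones 6_1 and 6_2.

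Higher in clone 14 were Pnliprp2, a pancreatic lipase relative, by 3.14 and 2.95 (SE 0.20), the matrix protein gene Mgp by 2.63 and 2.54 (SE 0.26), and Samd9l by 2.27 and 2.76 (SE 0.32) against clones 6_1 and 6_2. Tex19.1, a germ cell gene, was higher by 2.47 and 2.10 (SE 0.23) and the growth factor gene Bmp7 by 2.15 against each (SE 0.22). Against clone 6_1, 14 probes were higher and 9 lower in clone 14, with 2634 at an unadjusted p under 0.05. Against clone 6_2, 15 were higher and 9 lower, with 1807 at an unadjusted p under 0.05. Between clones 6_1 and 6_2 limma called 0 probes, with 452 at an unadjusted p under 0.05, and the unmoderated statistic also called 0. Whether clones 6_1 and 6_2 share an origin is not stated in the labels, and the 0 calls between them do not settle it. Mouse Pam differed by 0.08, 0.02 and -0.06 (SE 0.22) between clones 14 and 6_1, 14 and 6_2, and 6_1 and 6_2, and did not pass (adjusted p = 0.876, 0.985 and 0.998). The unmoderated statistic called 0 probes for clone 14 too, and with every probe kept 6 and 5 passed. Without the clone outside each contrast the counts were 308 for clones 14 and 6_1, 1032 for 14 and 6_2 and 2 for 6_1 and 6_2.

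**Figure D4:**
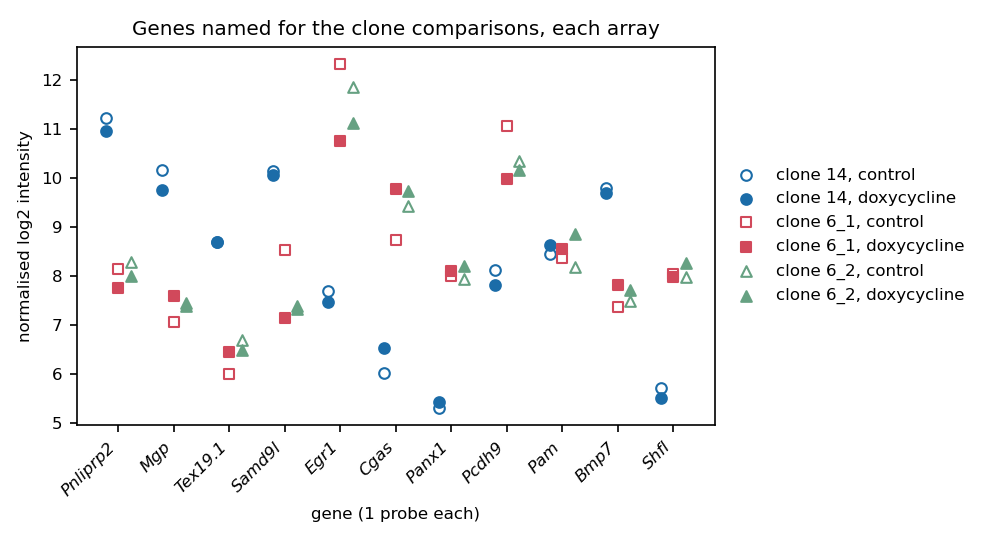
Normalised log2 intensity (vertical axis) of the genes named for the clone comparisons (horizontal axis, 1 probe each), with 1 point per array, coloured by clone, open for control medium and filled for doxycycline. Both arrays of clone 14 stand apart from the other 4 for Egr1, at 7.68 and 7.47 against 10.76 to 12.32, and for Pnliprp2, at 11.23 and 10.95 against 7.76 to 8.28.

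The responses of the clones resembled one another only in part. Across the 16902 probes, which are not independent replicates, the changes with doxycycline had a Pearson correlation of 0.419 between clones 14 and 6_1, 0.506 between 14 and 6_2 and 0.471 between 6_1 and 6_2 (Spearman 0.401, 0.479 and 0.445). The clones share no control array. In 8201 probes, or 48.5%, all 3 clones moved the same way, where 25% would if the clones were independent and rises and falls equally likely. The changes were wider in clone 6_1, with an SD across probes of 0.66, than in clone 14 (0.34) or clone 6_2 (0.37). Slpi read 2.35, 3.84 and 3.53 in clones 14, 6_1 and 6_2, and Krt73 1.80, 2.23 and 1.93. With 1 array per clone and medium, a difference between clones in any of these responses has no test.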

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

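All alternatives but removal of the gene length trend were chosen before the data were examined. All 53 calls with doxycycline kept their direction wherever they were tested, and the number kept as calls was 53 with median scaling, cyclic loess, trend and robust eBayes and without clone 14 or 6_2, 51 with offset 50, 50 without clone 6_1, 42 with the gene length trend removed, 35 with the authors' values, 34 with no background correction, 33 with no replicate block and 1 with no filter. The 32 rises became 19 with no replicate block, 77 with offset 50, 63 with median scaling, 50 with cyclic loess, 83 with trend and robust eBayes, 1 with no filter, 0 with an unmoderated paired statistic and 44 to 479 with a clone left out. The 21 falls became 32 with median scaling, 34 with trend and robust eBayes, 0 with no filter or the unmoderated statistic and 34 to 238 with a clone left out. The block changed no list call. With no filter, 45281 probes were tested, the prior degrees of freedom were 3.36 in place of 6.95, and the adjustment ran over more probes. Without clones 14 or 6_2 the prior degrees of freedom were infinite. The counts past the threshold rose there, while probes at an unadjusted limma p under 0.05 went from 3761 to 3226 and 2719. The cause of these shifts was not tested.

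For clones 14 and 6_1 the 23 calls became 45 with offset 50, 39 with median scaling, 6 with no filter, 36 with trend and robust eBayes, 0 unmoderated and 308 without clone 6_2. For 14 and 6_2 the 24 became 5 with no filter, 0 unmoderated and 1032 without clone 6_1, and for 6_1 and 6_2 the 0 became 2 without clone 14. The correlation of responses of clones 14 and 6_1 moved to 0.290 with no filter and 0.370 with the length trend removed. That of 14 and 6_2 moved to 0.575 with no background correction, 0.573 with the authors' values, 0.299 with no filter and 0.439 with detection p under 0.05. That of 6_1 and 6_2 moved to 0.520, 0.518 and 0.340 with the first 3 of these and to 0.418 with the length trend removed. The 6 lists became 3 to 8 with a clone left out, 3 with the length trend removed and 0 with an estimated correlation. Pcsk1 ran from -0.57 without clone 6_2 to 0.18 without clone 6_1, a reversal, and Pomc to -0.10 with cyclic loess, -0.19 with the authors' values and -0.11 with the length trend removed, where neither gene passed in any setting. Of 992 settings over 67 probes, 863 left the call as it was, 81 lost it and 44 gained it. Between clones 196 of 224 were the same and 28 lost the call, and of 356 settings of the lists 334 were the same, 20 lost and 2 gained the call, although neither variance setting enters the list test. A slide block was not run, since no slide is given in the sources used here. With the authors' values 8 named genes lost their call: Ly6g6c, H2al1m, Rfx2, Trp53rkb, Lrrc17, Speer2, Tox3 and Rpe.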

Other observations

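Families of genes that share a symbol stem were looked at only after the results were seen, and in this part the tests of families, of matched random lists and of the immediate early genes were chosen then. Of 10 families examined, 8 had an adjusted p under 0.05 by camera, each with an adjusted p = 0.361 with an estimated correlation. With doxycycline 71 of 72 mitochondrial ribosomal protein genes were higher, with a median change of 0.40, and so were 48 of 50 cytosolic ribosomal protein genes (0.37), 18 of 19 genes of Sm and LSm proteins and the related Snrpa, which serve several steps of RNA processing (0.54) and 7 of 7 subunit genes of RNA polymerase II (0.56). By camera these rises had adjusted p of 6.84e-14, 3.90e-09, 1.39e-06 and 7.94e-05. None of their genes passed over all probes. The polymerase genes measured were only Polr2d, Polr2e, Polr2f, Polr2g, Polr2h, Polr2j and Polr2l, so the 7 of 7 does not speak for the whole enzyme. All 4 medians stayed positive without background correction, with median scaling, cyclic loess and the authors' values, and without clone 6_1, where they were 0.26, 0.21, 0.35 and 0.42. With the gene length trend removed they were 0.29, 0.08, 0.39 and 0.38. Kinesin genes fell as a group, with 9 of 26 higher and a median of -0.24 (adjusted p = 0.00269), but 0 passed over all probes and the median lay at percentile 3.71 of lists matched on gene span and level, whose median was -0.12. Histone genes were higher in 36 of 43 cases (median 0.49, camera adjusted p = 9.14e-09), and 2 rose over all probes, H2al1e and H2al1m. The median lay at percentile 98.8 of matched lists but was 0.00 once the length trend was removed. Some H2ac genes had near-equal changes in clones 14, 6_1 and 6_2, as H2ac12 at 0.29, 2.28 and 0.85 and H2ac15 at 0.20, 2.27 and 0.93. Whether the probes tell such genes apart was not examined, so the 43 may not be separate measurements. Proteasome genes were higher in 26 of 33 cases (0.21, adjusted p = 0.00207), and of 196 zinc finger genes 65 were higher (-0.14, adjusted p = 0.00257), while the only call over all probes was a rise, of Zfp738 by 1.15 (SE 0.17, adjusted p = 0.0348). Without clone 6_1 the medians of the kinesin, histone, proteasome and zinc finger genes were -0.18, 0.39, 0.17 and -0.06. Keratins (4 of 8 higher, adjusted p = 0.611) and chaperonins (2 of 7 higher, adjusted p = 0.507) did not pass.

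Of the risen genes outside the naming rule, Pet100 at 1.24 (SE 0.19, limma adjusted p = 0.0459) and Fmc1 at 1.14 (SE 0.18, adjusted p = 0.0487) encode assembly factors of cytochrome c oxidase and of ATP synthase. Both were higher in each clone, Pet100 by 0.85, 1.62 and 1.25 and Fmc1 by 0.83, 1.19 and 1.41 in clones 14, 6_1 and 6_2. Lgals3, the lectin galectin-3, rose by 1.29 (SE 0.19). Ptn, the growth factor pleiotrophin, was not well above background on any control array and was at least 1.87-fold higher. Akr1c14, an aldo-keto reductase of steroids, fell by 1.15 (SE 0.18) and Dpp6, a potassium channel subunit, by 1.15 (SE 0.17).

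The largest change on the arrays belonged to a probe without a gene symbol in the annotation used here, ILMN_1217889. It rose by 5.29 on the log2 scale (SE 0.18), or 39.1-fold, with limma's adjusted p = 5.56e-06, and by 5.30, 5.01 and 5.56 in clones 14, 6_1 and 6_2. Its scanner signal was 184.3, 184.7 and 133.8 on the control arrays of these clones, above background on 2 of them, and 2995, 2447 and 2230 on the doxycycline arrays. It was the only call that remained with no filter. What it measures was not worked out here.

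The rise of the oxidative phosphorylation genes was set against 2 technical explanations, in tests chosen after the rise was seen, with the outcome that would count against each written down before the test was run. A trend with gene span as the whole cause is argued against, since the list's median of 0.53 lay at percentile 100 of 10000 random lists matched on gene span and level, of which the central 95% lay between 0.02 and 0.23. The control array of clone 6_1 as the whole cause is argued against too, since without that clone the median was 0.32, again at percentile 100 of matched lists. The genes of the matched lists were drawn singly, so these percentiles take no account of correlation within a list, estimated at 0.637 here. The lists were matched on span, which is not transcript length. What stays open is a difference in RNA quality or labelling that acts on short, abundant transcripts, which could also raise the ribosomal and RNA processing families above and go with the fewer probes above background on every doxycycline array (16196 to 16464, against 16851 to 17149 on the control arrays), and an effect of doxycycline itself, for which no cells without the transgene were analysed here. An effect of induced PAM-1 on genes of the respiratory chain is a hypothesis that these arrays cannot set apart from either, and the list did not pass with an estimated correlation (adjusted p = 0.889).

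The interferon and antigen presentation list was put to the same tests. Its median of 0.35 lay at percentile 99 of lists matched on gene span and level, and without clone 6_1 its median of 0.28 lay at percentile 99.5. Within the same limits of the matched lists, this argues against the span trend or that clone's control array as the whole cause. RNA quality, doxycycline and induced PAM-1 may each still contribute. The list also did not pass with an estimated correlation (adjusted p = 0.660).

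Egr1 and Fos were lower in clone 14 than in the other clones in both media. A weaker immediate early response of the clone 14 dishes as a whole, as handling of the dishes could give, would lower the other genes of that list too. Their median difference was -0.11 over 18 genes, 11 of which were lower, against -0.18 to 0.16 for the central 95% range of lists matched on level, which argues against a drop of the whole list. Klf2 at -1.34, Jun at -0.57, Klf4 at -0.45, Junb at -0.44 and Klf6 at -0.31 were lower as well. Ier3, Jund, Per1, Dusp4 and Crem were higher, by 0.70, 0.59, 0.33, 0.24 and 0.24. A lower response limited to some members therefore stays open, as does a lasting difference of the clone.

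Among the 10 splits of the 6 arrays into groups of 3, the real one gave 53 probes and the highest of the others 0, also among those that part every clone. As many probes came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05. The other splits mix the media within their groups, so any difference between the media adds to their residual spread. Their 0 calls therefore do not show what arrays without such a difference would give.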
